A study of Arabidopsis thaliana with 42 samples.

How the data were processed

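Messenger RNA was measured by RNA sequencing in 42 libraries from Arabidopsis thaliana seedlings of the Col-0 accession and of the link1link2 double mutant. LINK1 and LINK2, as the labels name the genes, were taken to be LNK1 and LNK2, a pair of light- and clock-regulated genes. Per the labels' protocols, seedlings were 9 days old and were grown on MS medium at 22 °C; the design text of the series gives a longer growth time for the continuous-light experiment, and this difference could not be resolved. The first experiment used continuous white light, with 3 wild-type and 3 mutant libraries. The second used long days of 16 h light and 8 h dark, harvested every 4 h from zeitgeber time 2 (ZT2, 2 h after lights on) to ZT22, with 3 libraries per genotype and time, which makes 36 libraries in 12 groups. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

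Per the labels' protocols, poly(A) RNA was selected, fragmented and reverse transcribed with random hexamers by the TruSeq RNA procedure, which was not stated to keep strand information. The authors deposited raw read counts per gene, 1 table for each experiment, without any normalization. Per the submitters' processing notes, the genome build was TAIR10. The aligner, the counting tool, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Each table held whole-number counts for 33602 loci, per the file headers from 1 alignment file per library. Of these identifiers, 32835 (97.7%) matched a locus tag of the TAIR10.1 reference annotation, which was used for gene symbols, for overlaps and neighbours of genes and for promoter sequences. No coordinates are reported. Because the counting was not stated to use strand, listed and named genes were checked for overlap with another locus. Of 308 such genes 76 overlapped one, and the values of the 31 whose other locus held at least 50% of their long-day counts are uncertain. Members of families of near-identical copies (LHCB1, RBCS, SAUR19 to SAUR24, KIN1 and KIN2, CBF1 to CBF3) are likewise uncertain, since shared reads may have been split between them.

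Columns were matched to groups by their names. Wild-type columns carried the accession's name and mutant columns a laboratory name that no label explains, so the mutant was assigned by elimination. LNK2 counts were lower in all 3 mutant columns than in all 3 wild-type columns in continuous light and at ZT2, ZT6, ZT10 and ZT22, and higher at ZT14 and ZT18. The column letters A, B and C could not be matched to the replicate numbers of the labels, so libraries are named by letter and letters were not used to pair samples. No pair of libraries of a group agreed within counting noise (chi-square per degree of freedom of 1.95 to 23.9), so each was counted as 1 sample.

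Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with the function filterByExpr, which left 20158 genes in continuous light and 20518 in long days, and library sizes were scaled with TMM factors. The quasi-likelihood test was applied with robust dispersion estimates, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Fold changes are log2 values of link1link2 over wild type with the standard error (SE) implied by the test, and levels are given as CPM (counts scaled by library size) with the standard deviation (SD) of 3 libraries. In long days, 1 model over the 12 groups with 24 residual degrees of freedom gave the contrast of the genotypes at each time, its mean over the 6 times, the test that it was the same at the 6 times, and the test of time of day within each genotype. The mean weighs the log2 ratio of each time equally, so it is not a ratio of average levels over the day. A second model with a 24 h cosine tested the difference in rhythm between the genotypes. Peak times came from cosine fits to log2 CPM. With 1 cycle sampled every 4 h, a peak time is an estimate from the cosine shape, and rhythms of other shapes are described by their values at each time.

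Calls of the experiments, which share no library, were compared with Fisher's exact test against independent lists. For the genes called in continuous light, peak times in wild type in long days were compared over 6 bins of 4 h with Fisher's exact test, two-sided. Fisher's exact test counts each gene as independent, which genes that vary together are not, so its p-values may be too small. There were 15 gene lists, written from textbook knowledge before the data were examined, as were the comparisons, the tests and the rule for naming genes. Some genes were on more than 1 list. COR27 and COR28 were on the evening clock and cold-response lists, and PIF4, PIF5 and PIL1 on the light-signalling and auxin lists. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, and the p-values of each were adjusted over the lists of a comparison. Besides the mutated genes and clock genes, the rule named the 10 genes with the largest rise and the 10 with the largest fall in continuous light and in the long-day mean (3 and 3 at each time) among called genes with a mean log2 CPM of at least 1 whose 3 mutant libraries all lay on one side of the wild-type libraries or whose long-day difference had the same sign at the 6 times, and the 10 genes with the smallest p for the tests of time dependence and rhythm. From a gene list it named up to 4 members with the smallest p, 2 per direction where both were called, and the members that the sentence rests on. A list of iron-responsive genes was written after the data had been seen and is described as such.

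The procedures were tested on simulated counts with the means and library sizes of the real libraries and 200 changed genes. In the simulated continuous-light comparison of 20024 genes, 95% of the genes changed 2-fold and 84% of those changed 1.5-fold were called, and 13.1% of the calls were unchanged genes, above the nominal rate. For the long-day mean over 20378 genes these values were 100%, 98% and 4.3%. At single times, 90% to 93% and 72% to 78% were called, and 5% to 10.9% of the calls were unchanged genes. For genes shifted by 1 sampling interval, 96.5% were called as time-dependent and 83% in the rhythm test, and cosine fits returned a median shift of 4.04 h for a true shift of 4 h.

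The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, calls of at least 2-fold, fits of single times, and leaving out each library or time. Added after the data had been seen were a block by column letter, the share of chloroplast counts as a covariate, and leaving out the 4 libraries with over 2% of their counts from chloroplast genes. Intervals of ratios and the floor of 3 counts, summed over the 3 libraries of a group, cover counting error only, at a confidence level of 95%.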

Results

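The data comprised messenger RNA counts of 42 libraries from Arabidopsis thaliana seedlings of the Col-0 wild type and of the link1link2 double mutant. The genes named LINK1 and LINK2 in the labels were taken to be LNK1 and LNK2. Both are induced by light, and their proteins act as coactivators together with MYB-like clock factors such as RVE8. In continuous light there were 3 libraries per genotype, with total counts of 11448934, 13668664 and 11455689 in wild type and 14911921, 13211090 and 12885386 in link1link2. In long days, 3 libraries per genotype were taken at each of 6 times (ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22, in hours after lights on). Their totals ran from 7259559 to 13576565. Chloroplast-encoded transcripts took 0.207% to 0.684% of the counts in continuous light and 0.429% to 3.31% in long days. This share was over 2% in 4 libraries, wild type ZT10 replicate B (3.31%) and link1link2 ZT2 replicate C (2.17%), ZT22 replicate A (2.07%) and ZT22 replicate C (2.28%).

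The mutated genes were examined first. In continuous light LNK2 was at 140 ± 0.568 CPM (SD, n = 3) in wild type and 16.9 ± 0.685 CPM in link1link2, a log2 fold change of -3.05 ± 0.06 (SE, edgeR adjusted p = 1.58e-18). LNK1 was at 39.9 ± 3.82 CPM against 24.1 ± 2.35 CPM (-0.74 ± 0.08, adjusted p = 8.39e-06). In long days wild-type LNK2 was highest at ZT2, at 729.5 ± 30.2 CPM, and fell to 7.36 ± 1.28 CPM at ZT18, whereas link1link2 held between 11.9 ± 1.29 CPM at ZT2 and 28 ± 1.83 CPM at ZT18. Wild-type LNK1 went from 251.8 ± 2.94 CPM at ZT2 to 0.464 ± 0.143 CPM at ZT18. In link1link2 it was at 74.1 ± 4.97 CPM at ZT2 and 4.91 ± 0.469 CPM at ZT18. The mutant therefore had less of both transcripts in the morning and more of both at ZT14 and ZT18. LNK1 overlaps the neighbouring locus AT5G64160 by 245 bases. Whether the remaining reads of either gene come from disrupted transcripts was not examined.

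**Figure D1:**
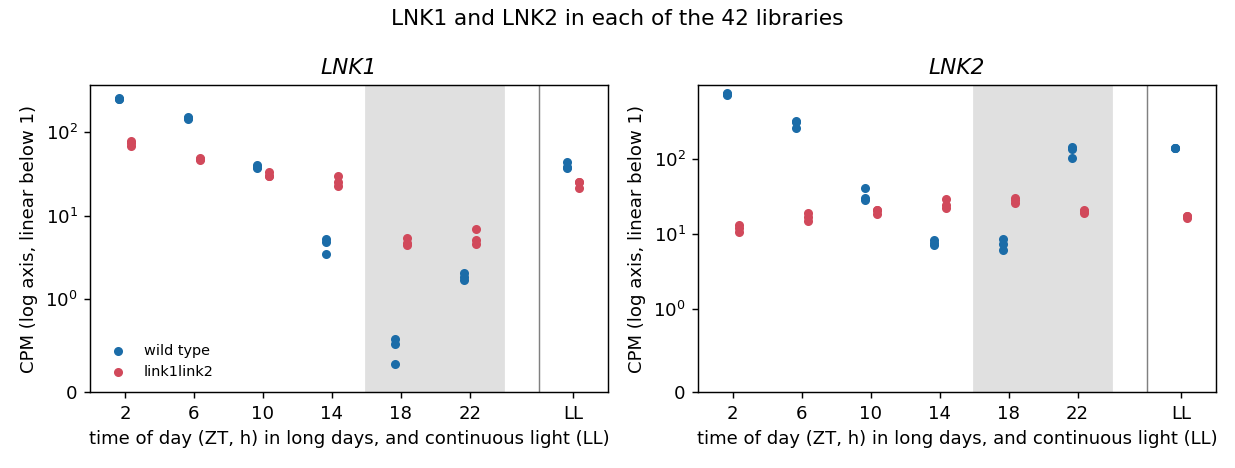
Level of LNK1 and LNK2 in each of the 42 libraries, in CPM on an axis that is logarithmic above 1 CPM, against time of day in long days (ZT, h, dark in grey) and in continuous light (LL). Each point is 1 library, and at ZT2 the link1link2 libraries lie near 11.9 CPM for LNK2 while wild type lies near 729.5 CPM.

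The comparison in continuous light asked how the transcriptome of link1link2 differed from wild type in the absence of light-dark cycles. No harvest time was available for these libraries. A difference in level therefore cannot be told apart from a difference in phase at harvest. Of the clock genes expressed around dawn, the MYB-like transcription factors CCA1 (94.2 ± 3.62 against 56.8 ± 5.18 CPM, SD, n = 3, log2 fold change -0.73 ± 0.07) and LHY (161.4 ± 3.18 against 81.5 ± 10.8 CPM, -0.99 ± 0.08) were lower in link1link2. Among the later genes, GI, which acts in the clock and in flowering, rose from 21 ± 1.03 to 44.9 ± 0.80 CPM (1.1 ± 0.07), and PRR7, a repressor of CCA1 and LHY, rose from 28.9 ± 1.29 to 54.6 ± 2.53 CPM (0.92 ± 0.07). ELF4, a part of the evening complex, fell from 23.6 ± 2.14 to 11.1 ± 0.366 CPM (-1.09 ± 0.09), and FKF1, a blue-light receptor of the F-box class, fell from 8.54 ± 1.14 to 3.81 ± 0.227 CPM (-1.16 ± 0.15). COR27, a cold-regulated repressor of clock genes, fell from 3.96 ± 1.01 to 0.402 ± 0.118 CPM (-3.30 ± 0.32, adjusted p = 8.83e-07).

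Of the 13 dawn-phased clock genes tested in continuous light, 2 rose, 5 fell and 6 were not called. Adjusted over the list alone, 2 rose and 6 fell. RVE1 (-0.80 ± 0.07) and RVE2 (-0.99 ± 0.07), MYB-like relatives of CCA1, fell with CCA1 and LHY, as did RVE8 (-0.38 ± 0.07), while LNK4, a relative of the mutated genes, rose (0.69 ± 0.10, adjusted p = 0.000108). The list median was 0.02, its mean was -0.21 and its test was downward, and that call was lost with an estimated correlation (adjusted p = 0.0693 with an estimated correlation). Of the 17 day- to evening-phased clock genes, 4 rose, 7 fell and 6 were not called, or 6 and 9 adjusted over the list alone. PRR3 also rose (0.69 ± 0.09) and PRR5 fell (-0.58 ± 0.10), both pseudo-response regulators of the family of TOC1. The list had no direction as a whole (camera adjusted p = 0.511, and adjusted p = 0.704 with an estimated correlation). The calls of 4 of these genes were lost when single libraries were left out. RVE7 (0.35) was not called whichever of the 6 libraries was left out (0.31 to 0.39). TOC1 (-0.26) was lost without wild type replicate A (-0.20), wild type replicate B (-0.28) or link1link2 replicate B (-0.21), LUX (0.35) without wild type replicate C (0.30) or link1link2 replicate A (0.27), and BOA (-0.60) without wild type replicate A (-0.51) or replicate B (-0.56).

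Outside the clock, the largest falls in continuous light among genes with a mean log2 CPM of at least 1 were those of AT3G01345, from 328.8 ± 12.1 to 0.59 ± 0.109 CPM (-9.10 ± 0.11, adjusted p = 4.25e-23), of MRD1, from 38.3 ± 1.62 to 0.612 ± 0.573 CPM, of the meiotic crossover gene HEI10, from 39.1 ± 1.70 to 2.02 ± 0.429 CPM, and of AT1G14250, from 48.7 ± 9.14 to 2.85 ± 0.355 CPM. MRD1 and HEI10 overlap each other by 1446 bases on opposite strands, so their counts cannot be assigned to either gene. MYBL2, a repressor of anthocyanin synthesis, fell from 12.1 ± 0.75 to 2.35 ± 0.969 CPM (-2.40 ± 0.18), and JMJD5, which encodes a JmjC-domain protein linked to the clock, fell from 33.6 ± 6.25 to 9.05 ± 0.765 CPM (-1.89 ± 0.14). Among the largest rises were THI2.2, a thionin, from 13.1 ± 3.13 to 52.5 ± 4.94 CPM (2.01 ± 0.15, adjusted p = 0.00011), AT2G05540, from 6.70 ± 0.641 to 24.0 ± 5.26 CPM (1.82 ± 0.19), and HFR1, a bHLH factor of light signalling, from 3.83 ± 0.426 to 9.57 ± 2.24 CPM (1.31 ± 0.17).

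Flavonoid and phenylpropanoid synthesis fell as a group in continuous light. Of 25 tested members, 20 fell, none rose and 5 were not called (21 fell adjusted over the list alone), and the list kept its call with an estimated correlation (adjusted p = 0.0182 with an estimated correlation). CHS, the entry enzyme of flavonoid synthesis, fell by 0.75 on the log2 scale (SE 0.08), FLS1, which makes flavonols, by 0.84 (SE 0.06), the flavonoid hydroxylase F3PH by 1.16 (SE 0.11) and PAL1, at the start of phenylpropanoid synthesis, by 0.52 (SE 0.06). Of 34 genes for light harvesting, the Rubisco small subunit and chlorophyll synthesis, 10 rose, 4 fell and 20 were not called (16 and 5 adjusted over the list alone), with LHCA1 (0.59 ± 0.07) and CHLH (0.61 ± 0.09) among those that rose and LHCB4.3 (-0.95 ± 0.13) among those that fell. This upward call was lost with an estimated correlation (adjusted p = 0.286 with an estimated correlation). Of 26 starch genes 2 rose, 7 fell and 17 were not called (4 and 14 adjusted over the list alone). The amylase AMY3 rose by 1.04 ± 0.08, whereas the debranching enzyme ISA3 (-0.80 ± 0.09) and DPE2, which metabolises maltose (-0.46 ± 0.06), fell. The downward call of the list was lost (adjusted p = 0.151 with an estimated correlation).

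Of 12 cold-response genes 4 fell, none rose and 8 were not called, with the same counts adjusted over the list alone. COR15A, which protects chloroplast membranes, fell from 28 to 7.78 CPM (-1.85 ± 0.13). COR27 (-3.30 ± 0.32) and COR28 (-1.20 ± 0.255), also counted on the evening clock list, were among the 4. The median of the list was 0.05, its mean was -0.51 and its test was downward, and the call was lost (adjusted p = 0.147 with an estimated correlation). Of 21 genes of auxin response and hypocotyl elongation 3 rose and 18 were not called (3 adjusted over the list alone), and the call was lost (adjusted p = 0.286 with an estimated correlation). PIF4 and PIF5, bHLH factors that promote elongation, rose by 0.80 ± 0.07 and 0.54 ± 0.07. Both are also on the light-signalling list. Of 31 light-signalling genes 4 rose, 2 fell and 25 were not called, with the same counts adjusted over the list alone, and HFR1 and BBX24 (0.52 ± 0.07) were among the genes that rose. Its test was not called (camera adjusted p = 0.0937). Of 24 flowering-time genes 3 rose, 5 fell and 16 were not called (4 and 5 adjusted over the list alone), with no direction as a list (camera adjusted p = 0.691). SOC1, a promoter of flowering, fell from 15.3 to 9.04 CPM (-0.76 ± 0.11), and the florigen gene FT had 40 counts in the wild-type libraries together and 2 in those of link1link2, a ratio of 22.0 with a counting interval of 5.7 to 188. Of 9 defence genes 2 fell and 7 were not called (5 fell adjusted over the list alone), and the downward call was lost (adjusted p = 0.076 with an estimated correlation). None of 15 root markers, 10 dividing-cell markers and 7 reference genes was called by edgeR (1 reference gene rose adjusted over the list alone), and no seed or embryo marker passed the filter.

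In total 1039 of 20158 genes differed in continuous light, 439 higher and 600 lower in link1link2, and 3399 had an unadjusted p under 0.05. Without wild type continuous light replicate B the count was 657. With a block by column letter, added after the data had been seen, it was 1888 (903 higher and 985 lower). A change of at least 2-fold was found for 101 of the 1039 genes.

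The long-day series asked at which times of day, and in which genes, the mutant differed under light-dark cycles. In wild type, CCA1 and LHY were already high before lights on, at 177.9 ± 14.6 and 626.5 ± 36.1 CPM at ZT22, whereas link1link2 had 22.2 ± 1.84 and 75.4 ± 1.78 CPM, log2 fold changes of -3.01 (adjusted p = 1.11e-25) and -3.05 (8.81e-28). By ZT10 the sign had changed, and both were higher in the mutant (CCA1 2.1 ± 0.562 against 12.3 ± 0.457 CPM, LHY 1.98 ± 0.844 against 8.63 ± 0.603 CPM). The evening genes were much reduced in link1link2 at ZT10, the end of the afternoon. TOC1, a repressor that peaks in the evening, was at 240.6 ± 5.57 CPM in wild type and 56.9 ± 1.5 CPM in the mutant, PRR5 at 107.4 ± 6.71 against 14.86 ± 2.48 CPM, ELF4 at 121.9 ± 9.80 against 12.5 ± 0.562 CPM, FKF1 at 123.3 ± 2.13 against 5.40 ± 0.748 CPM, and COR27 at 59.9 ± 2.63 against 0.153 ± 0.051 CPM.

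Late in the night TOC1 and LUX were higher in the mutant. At ZT22 TOC1 was at 71.3 ± 0.824 CPM in wild type and 136.1 ± 2.28 CPM in link1link2, and LUX, the DNA-binding part of the evening complex, at 20.8 ± 0.807 against 75.6 ± 2.74 CPM. GI and PRR7 were lower at ZT6 and higher at ZT14, where GI was at 12.4 ± 3.88 against 85.3 ± 3.93 CPM and PRR7 at 6.89 ± 0.571 against 80.9 ± 4.02 CPM. RVE8 was at 100.1 ± 11.6 against 34.4 ± 2.72 CPM at ZT22 and at 1.98 ± 0.481 against 15.7 ± 1.1 CPM at ZT10. LNK4 had 2 counts in the wild-type libraries at ZT14 and 238 in those of link1link2, a ratio of 123 with a counting interval of 33.6 to 1020. By time, the 13 dawn-phased genes gave 0 higher and 9 lower at ZT2, 10 and 1 at ZT10, and 1 and 8 at ZT22. The 17 day- to evening-phased genes gave 0 higher and 13 lower at ZT6, 0 and 14 at ZT10, and 13 and 0 at ZT22. In the long-day mean the dawn list had 4 genes higher, 4 lower and 5 not called (6 and 4 adjusted over the list alone), and the evening list 5, 8 and 4 (5 and 9 adjusted over the list alone). Neither list had a direction (camera adjusted p = 0.604 and 0.579).

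**Figure D2:**
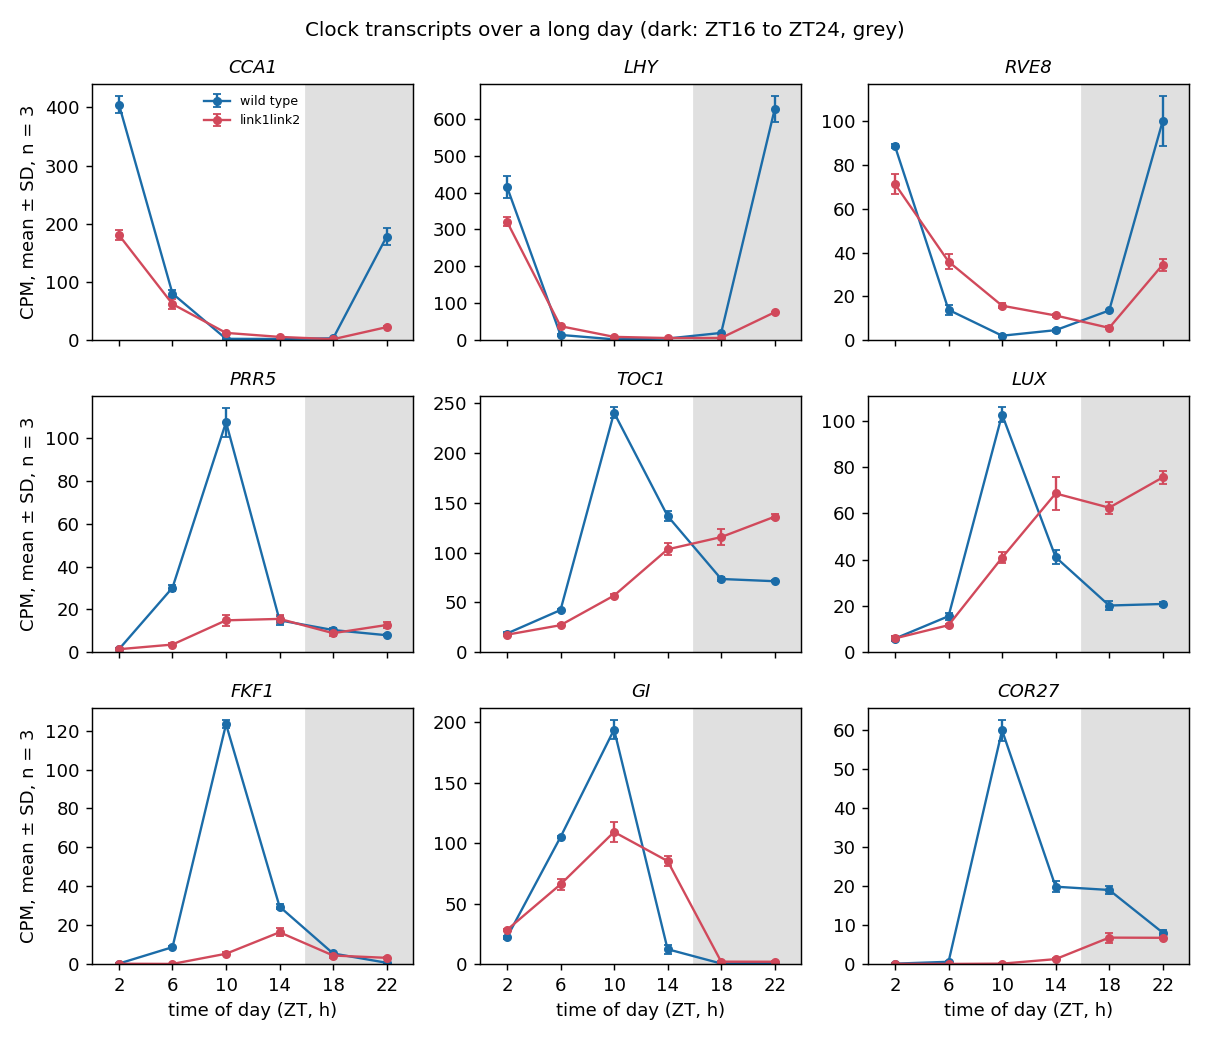
Levels of 9 clock transcripts over a long day in wild type and link1link2, in CPM (mean ± SD, n = 3) against time of day (ZT, h), with the dark period in grey. At ZT10 TOC1 is at 240.6 CPM in wild type and 56.9 CPM in link1link2, and at ZT22 LHY is at 626.5 and 75.4 CPM.

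Cosine fits placed most of these profiles later in link1link2. The peak of LHY moved from ZT23.62 to ZT1.84, a delay of 2.22 ± 0.37 h (SE), and that of CCA1 by 2.11 ± 0.42 h. Delays were 3.36 ± 0.45 h for RVE8, 3.71 ± 0.81 h for TOC1, 3.92 ± 1.06 h for PRR5, 3.73 ± 0.88 h for LUX, 3.70 ± 0.52 h for FKF1 and 4.46 ± 0.64 h for GRP7, an RNA-binding protein driven by the clock. Some of these fits were poor. The share of variance explained in wild type and link1link2 was 0.64 and 0.63 for PRR5 and 0.69 and 0.75 for LUX. In link1link2 the cosine peaks of TOC1 (ZT16.96) and LUX (ZT16.26) lay before their highest sampled levels, at ZT22 (136.1 and 75.6 CPM). PRR7 (1.51 ± 0.37 h), PRR9 (1.1 ± 0.43 h) and GI (1.11 ± 0.47 h) were delayed as well, and RVE1 (-0.42 ± 0.32 h), RVE4 (0.34 ± 0.56 h) and LKP2 (-0.93 ± 1.03 h) had shifts close to their SE. The fitted peak of ZTL was earlier in link1link2 (-2.61 ± 0.95 h), but its rhythm was not called as different (cosine test adjusted p = 0.225). Its wild-type peak-to-trough was only 0.32 on the log2 scale. The mutated LNK2, at 0.15 of its wild-type amplitude, was shifted by -11.43 ± 0.52 h. The amplitude in link1link2 was 0.68 of that in wild type for CCA1 and LHY, 0.56 for RVE8 and 0.54 for PRR7, and 0.98 for TOC1. For some clock genes it was larger than in wild type, among them LUX (1.16), BOA (1.04), COR28 (1.26) and RVE3 (1.12). These ratios have no SE, and the rhythm of RVE3 was not called as different (cosine test adjusted p = 0.221). The rhythm itself differed between the genotypes for 3148 genes by the cosine test, led by LNK2, COR413IM1, which encodes a cold-induced protein of the chloroplast envelope, BBX28, LHCB1.2, LHCB1.5, AMY3, LHCA4 and LHCA3. Without the 4 libraries of over 2% chloroplast counts it differed for 1647 genes.

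Counted by time, the number of genes that differed was 3306 at ZT2 (1750 higher, 1556 lower), 4119 at ZT6 (2072 and 2047), 4541 at ZT10 (2338 and 2203), 3016 at ZT14 (1584 and 1432), 4147 at ZT18 (2179 and 1968) and 6285 at ZT22 (3399 and 2886), of 20518 tested. Fitted alone, ZT2 gave 2028 genes and ZT14 gave 1704. At ZT22 2 of the 3 mutant libraries had over 2% chloroplast counts. Without the libraries of over 2% the count at ZT22 fell, but 1 mutant library was left there. A loss of power therefore cannot be told apart from an effect of those libraries. The other times then gave 2237 at ZT2, 4109 at ZT6, 3880 at ZT10, 3035 at ZT14 and 4150 at ZT18. With each single library left out ZT22 gave 5175 to 5425 genes, and with the chloroplast share as a covariate 5929. Of the changes of at least 2-fold, 309 were higher and 162 lower at ZT14, and 257 higher and 510 lower at ZT22. The genotype effect depended on time for 8596 genes and was seen in the mean over the day for 6954 (3732 higher, 3222 lower).

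**Figure D3:**
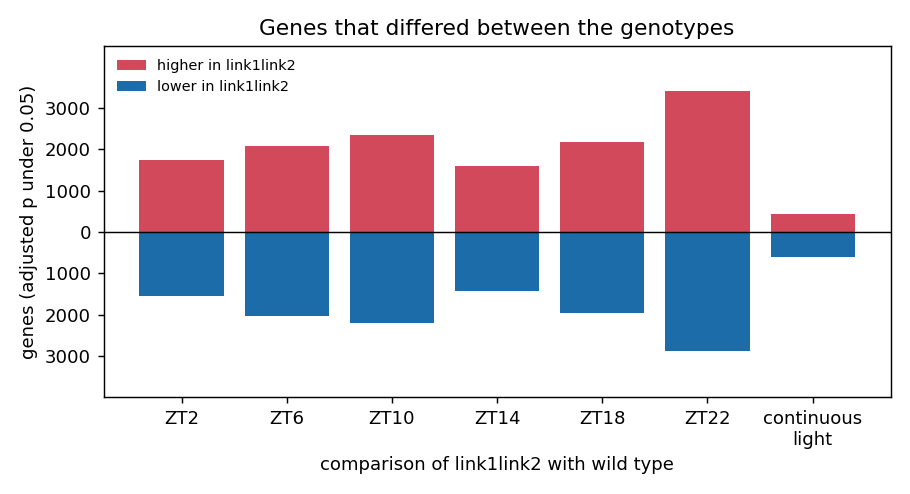
Number of genes higher (upward bars) and lower (downward bars) in link1link2 than in wild type at each time in long days and in continuous light, at an edgeR adjusted p under 0.05. At ZT22 3399 genes are higher and 2886 lower (3695 in all without the libraries of over 2% chloroplast counts), and in continuous light 439 and 600 (657 in all without wild type continuous light replicate B).

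The time-dependent genes with the smallest p included LHCA4, a light-harvesting protein of photosystem I, which at ZT14 was at 371.7 ± 16.6 CPM in wild type and 3889 ± 307.2 CPM in link1link2 (log2 fold change 3.39, adjusted p = 2.00e-29). OEP16-1, a channel of the outer chloroplast envelope, was at 271.4 ± 14.3 against 70.6 ± 2.58 CPM at ZT10, and MEE14 at 358.6 ± 22.9 against 68.8 ± 0.921 CPM. NDA1, a mitochondrial NAD(P)H dehydrogenase, was at 7.18 ± 1.37 against 65.6 ± 6.92 CPM at ZT10. COL5, a relative of CONSTANS, was at 9.16 ± 0.61 against 66.5 ± 3.54 CPM at ZT14. Among genes with the same sign at all 6 times, MRD1, AT1G14250, AT3G01345 and HEI10 again fell strongly, with mean log2 fold changes of -7.77 ± 0.07 for AT3G01345 and -4.92 ± 0.06 for HEI10. The value of HEI10 may be that of MRD1, since the loci overlap by 1446 bases and the counts cannot be assigned. MRD1 had 2326 counts in wild type and 2 in link1link2 at ZT22 (a ratio of 1070, counting interval 297 to 8860), and AT1G14250 had 195 and none at ZT18, at least 59-fold lower by a floor of 3 counts over the group. HMA2, a zinc-exporting ATPase, fell by 1.87 ± 0.09 (SE, adjusted p = 4.18e-19). Of those that rose, PI, a floral homeotic gene of low level in these seedlings, rose by 2.31 ± 0.24 (adjusted p = 6.73e-09), the blue copper protein gene BCB by 2.78 ± 0.44 and EARLI1, of the lipid-transfer type, by 1.89 ± 0.31. At single times the largest rises included PRR3 at ZT2 (10 against 118 counts), UF3GT and DFR of anthocyanin synthesis at ZT6 and ZT10, and the ethylene-synthesis gene ACS8 at ZT22. ACS8 had no counts in wild type and 322 in link1link2 at ZT22, at least 116-fold higher by a floor of 3 counts over the group.

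Genes of auxin response and hypocotyl elongation rose as a group in long days. Of 22 tested, 19 were higher in the mean over the day, 1 was lower and 2 were not called, with the same numbers of rises and falls adjusted over the list alone, and the call held (adjusted p = 0.000465 with an estimated correlation). At ZT6 none was higher and 13 were lower, whereas 11 were higher at ZT10, 12 at ZT14 and 20 at ZT18 and at ZT22, with none lower at these times. PIF4 was at 8.65 ± 0.42 CPM in wild type and 70.5 ± 5.23 CPM in link1link2 at ZT14, and at 1.3 ± 0.233 against 17.2 ± 0.768 CPM at ZT18. IAA29, an auxin-response gene, was at 14.7 ± 2.70 against 2.29 ± 1.44 CPM at ZT6 and at 1.70 ± 0.678 against 34.7 ± 3.87 CPM at ZT22. PIF5 rose by 1.03 ± 0.04 in the mean, YUC8, an enzyme of auxin synthesis, by 0.96 ± 0.09, and HB2, a homeodomain gene of shade avoidance, by 0.63 ± 0.07.

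Cold-response genes fell as a group, with 9 of 15 lower, none higher and 6 not called (9 lower adjusted over the list alone), and this call held as well (adjusted p = 0.0153 with an estimated correlation). By time, 10 were lower at ZT6, 12 at ZT10 and 6 at ZT14, with none higher, and 3 were lower and 1 higher at ZT18, whereas 5 were higher and none lower at ZT2. At ZT10 COR15A was at 638.7 ± 173.7 CPM in wild type and 24.0 ± 1.82 CPM in link1link2, and RD29A, a gene of the same response, at 667.5 ± 69.6 against 49.2 ± 5.73 CPM. GOLS3, of galactinol synthesis, had 126 against 1 counts (a ratio of 115, counting interval 20.2 to 4560). COR27 and COR28 are on this list and on the evening clock list.

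Flavonoid and phenylpropanoid genes changed sign over the day. At ZT6, 17 of 24 were higher in link1link2 and 2 lower, and at ZT10 15 were higher and 1 lower, whereas at ZT18 1 was higher and 12 lower and at ZT22 none was higher and 18 lower. CHS was at 87.6 ± 6.94 against 159.5 ± 19.1 CPM at ZT6 and at 133.0 ± 5.64 against 22.7 ± 4.34 CPM at ZT22. In the mean over the day 4 were higher, 10 lower and 10 not called (5 and 10 adjusted over the list alone). The list median was -0.03, its mean was 0.07 and its test was downward, a call lost with an estimated correlation (adjusted p = 0.463 with an estimated correlation). MYBL2, which represses this pathway, was lower in the mutant from ZT2 to ZT10 (85.7 ± 11.1 against 5.99 ± 2.00 CPM at ZT6) and higher from ZT14 to ZT22.

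Light-harvesting, Rubisco small subunit and chlorophyll genes were mostly lower in the morning (1 of 35 higher and 25 lower at ZT2) and mostly higher in the evening (24 higher and 3 lower at ZT14), with 12 higher and 15 lower at ZT22. LHCB2.2 was at 40.9 ± 3.53 CPM in wild type and 1133 ± 72.9 CPM in link1link2 at ZT14. Over the day 20 were higher, 9 lower and 6 not called (22 and 9 adjusted over the list alone), and the upward call was lost (adjusted p = 0.0678 with an estimated correlation). Copies of LHCB1 and RBCS are nearly identical, so their single values are uncertain. Of 26 starch genes 5 were higher, 16 lower and 5 not called (5 and 18 adjusted over the list alone), and the downward call was lost (adjusted p = 0.0722 with an estimated correlation). GWD1, which phosphorylates starch for its breakdown, was at 857.8 ± 56.4 against 204.4 ± 8.68 CPM at ZT10 (mean log2 fold change -0.70 ± 0.03), and DPE2 (-0.55 ± 0.03), ISA3 (-0.67 ± 0.05) and the phosphatase gene SEX4 (-0.46 ± 0.05) fell with it.

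**Figure D4:**
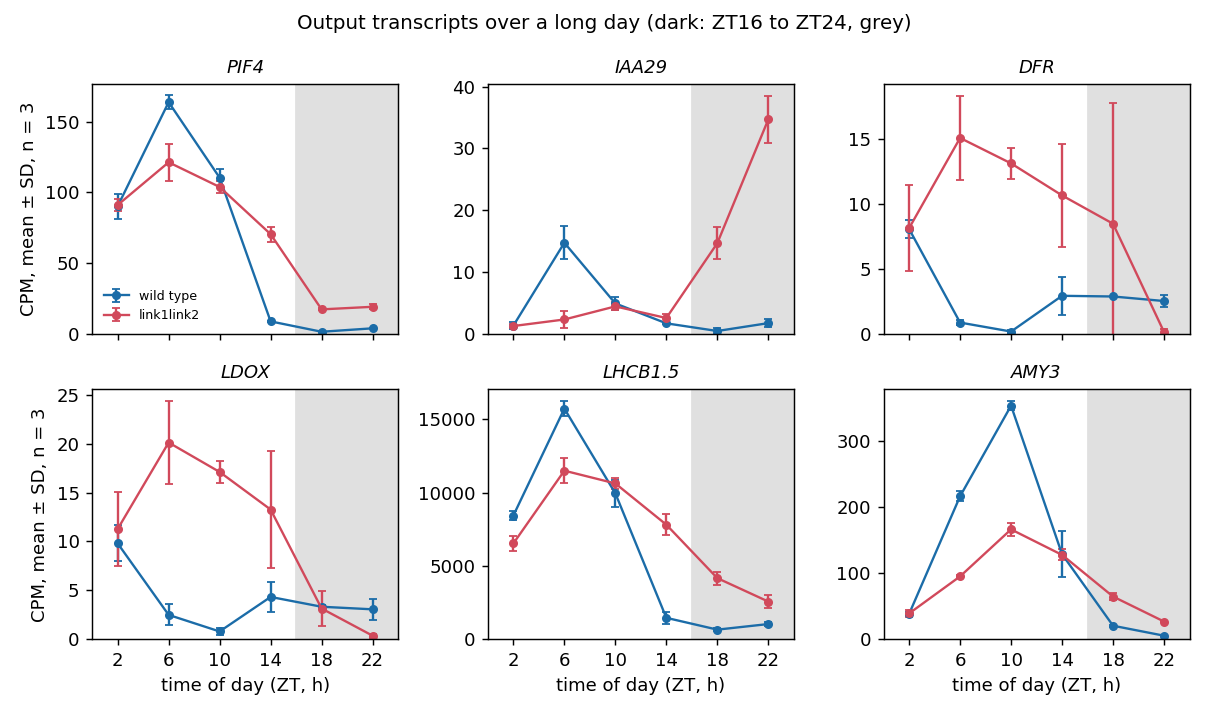
Levels of PIF4, IAA29, DFR, LDOX, LHCB1.5 and AMY3 over a long day in wild type and link1link2, in CPM (mean ± SD, n = 3) against time of day (ZT, h), with the dark period in grey. At ZT14 PIF4 is at 8.65 CPM in wild type and 70.5 CPM in link1link2, and at ZT22 IAA29 is at 1.70 and 34.7 CPM.

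Of 24 flowering-time genes 5 were higher in the long-day mean, 6 lower and 13 not called, with the same rises and falls adjusted over the list alone, and no direction as a list (camera adjusted p = 0.579). FT was at 3.04 ± 0.25 CPM in wild type at ZT14, with 81 counts against 3 in link1link2, a ratio of 26.2 with a counting interval of 8.64 to 129. At ZT10 the counts were 82 against 2 (37.3, 10.0 to 313). SOC1 fell by 1.11 on the log2 scale (SE 0.08), and CDF2, a repressor of CO and FT, rose by 0.65 ± 0.07. Of 31 light-signalling genes 10 were higher, 7 lower and 14 not called (11 and 7 adjusted over the list alone), among them HFR1 (1.07 ± 0.06), BBX24 (0.68 ± 0.03) and BBX22 (-0.67 ± 0.04), and the upward call was lost (adjusted p = 0.0722 with an estimated correlation). Of 9 defence genes 6 fell and 3 were not called (6 fell adjusted over the list alone), including LOX2 of jasmonate synthesis (-0.74 ± 0.12), PAD4 (-0.28 ± 0.05) and VSP2 (-0.71 ± 0.12), and this call was lost (adjusted p = 0.159 with an estimated correlation).

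Of 15 root markers 3 were lower and 12 not called in the long-day mean (2 lower adjusted over the list alone), and at ZT22, the time of 2 of the 4 libraries of over 2% chloroplast counts, 1 was higher and 6 lower. The iron transporter gene IRT1 and the ferric reductase gene FRO2 fell by 1.19 ± 0.19 and 1.31 ± 0.20 in the mean. The list as a whole was not called (camera adjusted p = 0.506). Of 10 dividing-cell markers 1 was higher, 2 lower and 7 not called, with the same counts adjusted over the list alone, and none of 3 seed and embryo markers was called. Of 7 reference genes 2 were higher, 1 lower and 4 not called, again the same adjusted over the list alone, and EF1A (0.17 ± 0.03) had the smallest p. The mutated genes themselves were 1 higher (LNK1, 0.61 ± 0.07, and not called without ZT18, at 0.06) and 1 lower (LNK2) in the mean. The value of LNK1 is a mean of log2 ratios in which each time counts equally, and not a rise of its average level. LNK1 was lower in link1link2 at ZT2 (251.8 against 74.1 CPM), ZT6 (148.4 against 47.8 CPM) and ZT10 (39.1 against 31.1 CPM). It was higher at ZT14 (4.58 against 26.2 CPM), ZT18 (0.464 against 4.91 CPM) and ZT22 (1.86 against 5.56 CPM).

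Time of day itself altered the level of 16402 genes in wild type and 17184 in link1link2, with 15170 genes in both, 1232 in wild type alone and 2014 in link1link2 alone. Whether a gene was called in 1 genotype and not in the other was not tested as a difference. Over 887 genes with well-fitted cosines in both genotypes the median shift of the peak was 0.79 h (quartiles -0.39 and 1.73 h), and 605 (68.2%) peaked later in link1link2. By wild-type peak time the median shift was 1.99 h around ZT2 (147 genes), 1.22 h around ZT6 (251), -0.29 h around ZT10 (220), 1.37 h around ZT14 (70), 0.68 h around ZT18 (87) and -0.06 h around ZT22 (112).

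The experiments share no library, so their calls were compared directly. Of 19982 genes tested in both, 226 were higher in link1link2 in both experiments, where independent lists give 80.3 (Fisher's exact test, two-sided, odds ratio 4.99, BH-adjusted p = 1.08e-56 over 4 tests), and 396 were lower in both, where independent lists give 94.5 (odds ratio 12.0, adjusted p = 3.14e-176). Opposite calls were fewer than independent lists give, with 51 higher in continuous light and lower in long days (69.8, odds ratio 0.69, adjusted p = 0.012) and 37 the other way (108.8, odds ratio 0.29). PIF4, PIF5, HFR1 and THI2.2 were among the genes higher in both, and SOC1, FLS1, CHS, ISA3 and COR15A among those lower in both. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.467 and a Spearman rho of 0.255. Counting changes of at least 2-fold, 41 genes were shared.

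Genes that fell in continuous light tended to be those with an afternoon or evening peak in wild-type long days. Whether this reflects level or phase at the unknown time of harvest cannot be told apart. Of 573 such genes with a time-of-day change, 28.3% (95% exact interval 24.6% to 32.2%) peaked around ZT10 against 16.9% of the other genes (odds ratio 1.94, BH-adjusted p = 3.98e-10 over 12 tests), and 20.6% around ZT14 against 12.8% (odds ratio 1.77, adjusted p = 8.06e-07). They were less often found around ZT18 (10.8% against 20.3%) and ZT22 (8.6% against 18.5%). The intervals and p-values count genes as independent, so they may be too narrow. No limit on the quality of the cosine fit was set for these peak times. Of 399 genes that rose, 20.6% peaked around ZT2 against 12.3% (odds ratio 1.84, adjusted p = 1.02e-05, a call lost among genes with a peak-to-trough of at least 1, at 18% against 15%, odds ratio 1.25, adjusted p = 0.385) and 25.8% around ZT6 against 18.8% (odds ratio 1.5, adjusted p = 0.00115), and 5.8% around ZT14 against 13.2% (odds ratio 0.40, adjusted p = 5.99e-06).

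**Figure D5:**
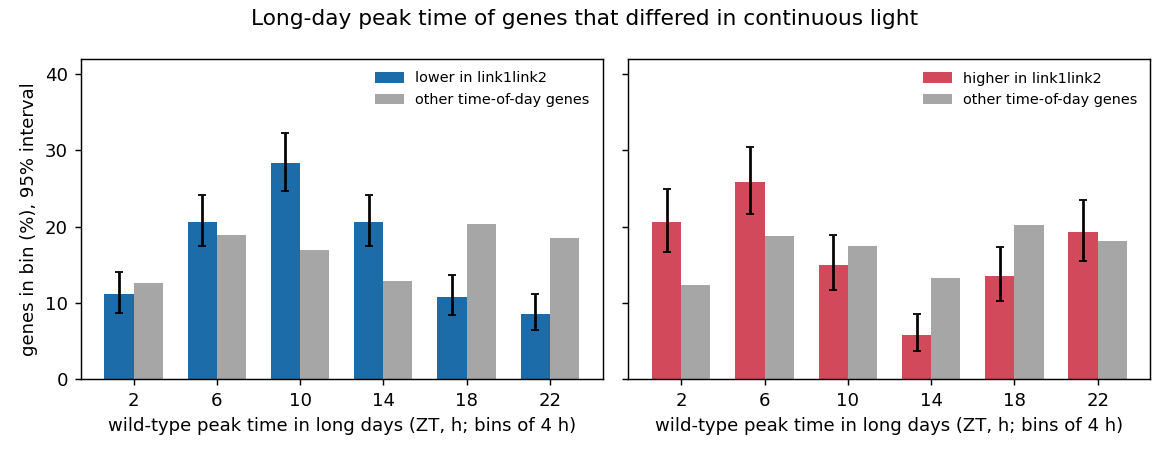
Share of genes (%, with 95% exact intervals) by their wild-type peak time in long days, in bins of 4 h, for genes lower and genes higher in link1link2 in continuous light, beside the other time-of-day genes (grey). Genes that were lower are most frequent around ZT10 (28.3% against 16.9%), and genes that were higher around ZT6 (25.8% against 18.8%). The intervals count each gene as independent.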

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

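The test without the 4 libraries of over 2% chloroplast counts was chosen only after the result was seen. In long days the difference between link1link2 and wild type was tested for being the same at the 6 times, and it changed with the time of day for 8596 genes. This calls for a closer look because the same contrast had different effects at different times. Of these genes, 3163 (36.8%) were called higher in the mutant at some times and lower at others, and 4107 were also called in the mean over the day. Chance in how these libraries were grouped is argued against. Among 50 splits of the libraries within times only the real split (1 of 50) gave as many genes, with 2155 in the highest other split. Such splits cannot address a chance difference between cultures, since the replicates may be technical.

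The libraries of over 2% chloroplast counts are argued against as the whole of this pattern, since 7147 genes were called without them. A later phase of the wild-type profile is a candidate explanation. The difference followed the earlier wild-type level more than the later one at 4 of the 6 times, for example at ZT6 (r = 0.625 against 0.005), but at ZT22, counted among the 4, it followed neither (-0.011 against -0.324), and at ZT18 it followed the later level (-0.342 against 0.296). A shift of a 24 h cosine leaves the mean over 6 evenly spaced times unchanged. Of the 8596 genes, 4107 were also called in that mean. For these genes this would argue against a phase shift alone only if their profiles followed a cosine, which was not examined for them. Time of day altered 15170 genes in both genotypes, and 887 met the limits set for the cosine fit and its peak-to-trough. The mean therefore does not decide the question. The comparison with earlier and later levels does not separate a phase shift from changes in level or shape either, since it uses steps of 4 h. The biological difference between the genotypes stays open as the remaining explanation.

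The daily rhythm, tested as a 24 h cosine, differed between the genotypes for 3148 genes, again a difference of the same measure between groups. Chance in how these libraries were grouped is argued against here as well, with the same limit. Only 1 of 50 splits, the real one, gave as many, and the highest other split gave 1 gene.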

How the results depend on the processing

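A block by column letter, the chloroplast share as a covariate, and leaving out the 4 libraries of over 2% chloroplast counts were chosen after seeing the data. The planned block by the replicate number of the labels was not run, because the columns could not be matched to those numbers. The block by column letter moved the count in continuous light from 1039 to 1888 genes, of which 1035 were among the 1039. The correlations of the deviations of libraries of the same letter were 0.133, 0.051 and 0.103 in continuous light. They were over 0.1 in 4 of 21 pairs across both experiments (-0.32 to 0.133), and the letters were not taken to pair the libraries. In continuous light all were positive and the block raised the count, so a factor shared by libraries of the same letter cannot be excluded there. Calls of at least 2-fold numbered 101 in continuous light, 216 in the long-day mean, 255 at ZT2, 525 at ZT6, 770 at ZT10, 471 at ZT14, 538 at ZT18 and 767 at ZT22, with 41 genes shared between the experiments, since this limit keeps part of the calls by construction. Of these calls 28.7% were higher in continuous light, 65.6% at ZT14 and 33.5% at ZT22, against 42.3%, 52.5% and 54.1% of all calls. Fitted alone, ZT2 gave 2028 and ZT14 gave 1704 genes, fewer than the 3306 and 3016 of the joint fit, whereas ZT6 (4303), ZT10 (5095), ZT18 (4730) and ZT22 (6434) gave more, and the cause was not tested. Without the libraries of over 2% chloroplast counts, ZT22 gave 3695 genes against 6285 and the rhythm test 1647 against 3148, and the cause was not tested. There link1link2 had 1 library at ZT22, which is assumed to vary like the other groups. With an estimated correlation, 5 of 16 list calls were kept. Among the 5 was, in both experiments, the list of the 2 genes altered in the mutant by design. The others were flavonoid and phenylpropanoid synthesis in continuous light, and the cold-response list and the auxin and elongation list in long days.

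Leaving out each library gave 657 (without wild type continuous light replicate B) to 929 genes in continuous light. In long days it gave 6638 to 7114 for the mean, 8151 to 8958 by time, 2499 to 3246 for the rhythm, 2302 to 3214 at ZT2 and 5175 to 5425 at ZT22, all within 1.5 times the count of all libraries. DESeq2 gave 711, 6124 and 7625 genes in continuous light, in the mean and by time, and the covariate 695 in continuous light, and no call of a named gene changed sign under either. Counting each named or listed gene in each comparison, DESeq2 left 2367 values on the same side of the threshold, with 56 calls lost and 44 gained. RLE scaling, for which the 29 list tests were counted as well, left 2492, with 2 and 2. Depth limits genes at a few counts, whose fold changes have wide counting intervals.

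A mean over fewer times changed sign for some genes, by construction where the genotype difference changes over the day. Without ZT6 this was CRY1 (0.077). Without ZT10 it was TOC1 (0.081), OEP16-1 (0.039), AT1G64500 (-0.149), RVE8 (-0.095), BOA (0.307), GRP7 (0.289), RCA (-0.141) and GBSS1 (-0.285). Without ZT14 it was CDF3 (-0.308), PIF7 (-0.124), LHCB4.2 (-0.02) and CRD1 (-0.002). Without ZT18 it was LHY (0.085), SPA3 (0.074), SPA4 (0.167), HYH (0.047) and GUN4 (0.093). Without ZT22 it was LHY (0.346), AMY3 (-0.122), CCA1 (0.294), RVE4 (0.112), GRP8 (-0.007), SPA3 (0.095), SPA4 (0.152), HYH (0.121), 4CL2 (0.125), UGT78D2 (0.173) and GUN4 (0.144). AMY3 at ZT14, which was not called, ran from -0.133 to 0.23 when each library was left out, and the highest value, without wild type ZT14 replicate B, was called. The cause was not tested.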

Other observations

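The tests of the mutant line and the clock defect, of the iron-responsive genes as a group and of the genes beside LNK1 and LNK2 were chosen only after the result was seen. Genes induced by iron shortage were examined with a list written after the data had been seen. Of its 17 genes, 14 were lower in the long-day mean, none was higher by edgeR and 3 were not called (median log2 fold change -0.63, mean -0.86), and in continuous light 8 were lower, none was higher and 9 were not called (median -0.72, mean -0.83). The bHLH factors of this response were among them in long days, with bHLH38 at -1.53 ± 0.21 (SE, adjusted p = 2.26e-06), bHLH39 at -1.18 ± 0.17, BHLH100 at -1.84 ± 0.33 and BHLH101 at -1.33 ± 0.19. BTS, which encodes an E3 ligase of iron sensing, fell by 0.51 (SE 0.08), the transporter gene OPT3 by 0.45 (SE 0.07) and NAS4, of nicotianamine synthesis, by 0.48 (SE 0.07). OPT3 (-0.42 ± 0.07, adjusted p = 0.000427) and NAS4 (-0.58 ± 0.08, adjusted p = 7.02e-05) fell in continuous light as well. The genes of the iron-storage protein ferritin went the other way, with FER1 higher by 1.15 ± 0.15, FER4 by 0.78 ± 0.11 and FER3 by 0.17 ± 0.04 in the long-day mean. In continuous light FER4 was called higher (0.71 ± 0.12, adjusted p = 0.00124), and FER1 (0.77 ± 0.18, adjusted p = 0.0936) and FER3 (0.04 ± 0.07, adjusted p = 0.875) were not called. The ferritin list had an unadjusted camera p of 0.0572 in long days and 0.0666 in continuous light with an estimated correlation. The loci of bHLH38, BHLH101, MYB10, MYB72, FER1 and FER4 overlap other loci, so their values are uncertain. F6'H1 and FRO3 overlap loci with 19.2% and 8.3% of their long-day counts. BHLH101, MYB10 and MYB72 were among the 8 genes called lower in continuous light. They belong to the reduced list of 11 genes tested below.

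CIPK20, a kinase gene that works with calcium sensors, was at 113.6 ± 5.05 CPM in wild type and 17.3 ± 2.2 CPM in link1link2 at ZT6, and it fell in continuous light (-1.84 ± 0.12, adjusted p = 9.42e-09). AT1G69140 had 152 counts in wild type and none in link1link2 at ZT6, at least 48-fold lower by the floor of 3 counts over the group. SAUR22, a small auxin-induced gene, went from 1 count in wild type to 98 in link1link2 at ZT18, a ratio of 108 with a counting interval of 18.9 to 4310. CBF1, a regulator of the cold response, had 55 counts against 3 at ZT10 (ratio 16.7, interval 5.42 to 83.4).

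Whether iron shortage genes are lower as a group was tested by camera with an estimated correlation. The unadjusted p was 0.0182 in the long-day mean and 0.0444 in continuous light, and 0.0236 and 0.0376 for the 11 genes left after removing the 6 that drew attention to the pattern. The libraries of over 2% chloroplast counts are argued against as its source, since the long-day median was -0.63 without them. The 15 root markers, which include IRT1 and FRO2, had medians of -0.03 in the long-day mean (3 lower) and 0.04 in continuous light, and at ZT22 1 was higher and 6 were lower (median -0.25). No biological explanation of the pattern was tested.

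MRD1, HEI10, AT3G01345 and AT1G14250 were almost absent from link1link2 in both experiments. For HEI10 a candidate explanation is reads shared with the overlapping MRD1, since the counts of HEI10 beyond those of MRD1 in long days were 1.38 CPM in link1link2 and -0.388 CPM in wild type. For the other 3 genes, a difference of the mutant line unrelated to the clock cannot be told apart from a loss through the clock defect. The highest mutant library held 6.69% of the wild-type mean (AT1G14250), and the difference changed with the time of day for 0 of the 3 genes by edgeR (adjusted p = 0.115, 0.77 and 0.708), which leaves both open because the design has no other mutant to compare.

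The genes beside the mutated loci were also examined. Of the 4 nearest tested neighbours, 2 were higher in continuous light, where 2.2% of tested genes were. These were AT3G54510 beside LNK2, at 0.693 CPM in wild type and 3.02 CPM in link1link2 (2.13 ± 0.29, adjusted p = 5.05e-05), and AT5G64180 beside LNK1 (0.55 ± 0.10, adjusted p = 0.00154). AT3G54510 drew attention to these genes, and without it 1 of 3 was higher (exact binomial p = 0.0639), while in the long-day mean, where 3732 of 20518 tested genes were higher, the 4 were called higher (AT5G64160 0.29 ± 0.04, AT5G64180 0.52 ± 0.06, SKIP5 0.20 ± 0.04 and AT3G54510 2.06 ± 0.24). AT5G64160 overlaps LNK1 by 245 bases, so its counts may include reads of LNK1. An effect of the altered loci on adjacent genes stays open as a hypothesis, because it was seen in these same genes before it was tested.

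The evening element AAAATATCT was sought within 500 bp upstream of genes lower in continuous light. It was found for 9% of 597 lower genes and 4.3% of 18981 genes without a call (Fisher's exact test, two-sided, odds ratio 2.22, BH-adjusted p = 3.05e-06 over 4 tests), and for genes that rose the odds ratio was 1.13 (adjusted p = 0.733). The same bases in reversed order were found for 3.9% and 2.4% (Fisher's exact test, odds ratio 1.61, p = 0.0428, adjusted p = 0.0856), a smaller excess. In the 6 bins of wild-type peak time the odds ratio of the element was 1.2 around ZT2, 1.91 around ZT6, 2.08 around ZT10, 1.61 around ZT14, 1.64 around ZT18 and 0.92 around ZT22 (Fisher's exact test, unadjusted p = 0.685, 0.0729, 0.00355, 0.143, 0.436 and 1). A role of the motif in the falls is a hypothesis that stays open, since the reversed order passed 0.05 before adjustment but with a smaller odds ratio.

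Other splits of the samples were counted for the remaining results. Chance in how these libraries were grouped is argued against for the long-day mean (1 of 50 splits, 6954 genes against 1285 in the highest other). The same holds for time of day in wild type (1 of 50, 16402 against 656) and in link1link2 (1 of 50, 17184 against 2357). Chance differences between cultures cannot be addressed by such splits. For the gene lists in the long-day mean chance cannot be excluded, since 3 of 50 splits gave as many list calls by camera at the preset correlation, with 8 in the real split and 9 in the highest other. The 6 libraries in continuous light and at each time make 10 splits, too few for a share under 0.05, and each time 1 of the 10, the real one, had as many calls. The real and the highest other values were 1039 and 5 genes and 8 and 4 gene lists in continuous light, 3306 and 251 genes at ZT2, 4119 and 0 at ZT6, 4541 and 0 at ZT10, 3016 and 50 at ZT14, 4147 and 0 at ZT18 and 6285 and 0 at ZT22. In both experiments the list of the mutated genes was among the 8 lists called in the real split.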
